A study of Mus musculus with 4 samples.

How the data were processed

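The series holds 4 RNA libraries from mouse bone marrow-derived dendritic cells, which are antigen-presenting cells grown in culture from bone marrow precursors. Methylated RNA immunoprecipitation sequencing (MeRIP-seq) pulls fragments that carry N6-methyladenosine (m6A) out of fragmented RNA with an antibody, and compares them with the fragmented RNA before the pull-down, called the input. By their labels, 2 libraries were m6A immunoprecipitates and 2 were inputs, numbered as replicates 1 and 2 in each group. Per the labels' protocols, polyadenylated RNA was selected and chemically fragmented, the libraries were sequenced as read pairs, low-quality reads were removed with Trimmomatic and ribosomal RNA reads were filtered with Bowtie2. The submitters' processing notes also name STAR, HOMER, ChIPseeker and deepTools and the genome build GRCm39. The role of those tools, the tool versions, the peak caller, its threshold and whether replicates were pooled for the calls are not given in the sources used here. Nothing in the labels says whether the replicates came from separate cultures or animals.

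The authors deposited 1 list of 9028 peaks for the whole series, with 6 columns giving the chromosome, start, end, name, score and strand of each peak. The score in the deposited list was 0 in every row, so the list carries no height, fold enrichment or p-value, and no value belongs to a single library. The depth behind each peak, the spread between replicates and the level in the input libraries are therefore unknown here, and no comparison between libraries was made. The other deposited values were genomic positions. The list has no block columns, so a span that crosses an intron includes it, and a span is not the length of the enriched RNA. Rows were ordered neither by position nor by strand.

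The only gene table at hand described GRCm38.p6, another build than the one the processing notes name, and held no exons, strand or sequence. Of the 9018 peaks on the autosomes and X, 53.8% lay inside a protein-coding gene of that table at the listed positions. After all positions were shifted by 20 to 500 kb either way, in 10 shifts, the share was 53.4% to 54.0% for shifts of 20 or 50 kb and 47.5% to 53.4% for shifts of 100 to 500 kb. The share at the listed positions was within the range of the shifts of 20 and 50 kb and above that of the larger shifts. Because the builds differ, nuclear peaks were reported by GRCm39 position and were not given gene names. Mitochondrial peaks were named, because 12 of their 18 edges coincided to the base with edges of mitochondrial genes in the table. That match also showed that starts in the list count from 0. All positions are printed counting from 1.

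Before the data were examined, 8 results, 57 alternatives and 21 gene lists had been fixed. These covered the regions of the transcript, the stop codon, the 5′ end, the DRACH sequence motif, long exons, peak scores, and the genes and gene lists with a peak. None could be computed without transcript models and sequence of GRCm39 or a score that varies, so no list was evaluated and the fixed rule for named genes could not be applied. The rule would have named the genes with the strongest peaks, the genes with the most peaks and the leading members of each list. All results below, and all of their alternatives, were chosen after seeing the data. In place of the rule, every mitochondrial peak was named, together with the loci with 8 or more peaks, the 5 widest peaks and the 5 windows of 1 Mb with the most peaks.

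Peaks of 1 chromosome and strand were joined into a locus where the gap between spans was at most 10 kb (10000 nt). A locus stands in for a gene but can hold parts of several genes, or part of 1. The share of loci on each chromosome was divided by that chromosome's share of the 21631 protein-coding genes that the GRCm38.p6 table places on the autosomes and X. That table was used here only for which chromosome a gene is on. Each ratio was tested with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes and a threshold of 0.05. Strand shares were tested in the same way against 50%. In loci with 2 or more peaks, the spans of the 5′-most and 3′-most peak were compared with a two-sided exact sign test. Overlaps of at least 1 nt between peaks on opposite strands were counted, and compared with 1000 lists in which each minus-strand peak was shifted by 20 to 200 kb. Among pairs of up to 1000 nt, the number with both edges within 30 nt was compared with 10000 draws in which every overlapping offset was equally probable (one-sided). Intervals are exact Clopper-Pearson intervals at 95% and cover counting error only. They treat the counted loci, peaks or pairs as independent and describe this list, not the spread between libraries. Peaks of 1 locus share a chromosome and strand by construction. Where single peaks were counted, p-values are therefore too small and intervals too narrow.

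The chromosome share test, the test of coincident edges and the comparison of 5′-most with 3′-most spans were tested on simulated data, and the other tests were not. With the share of X halved in 200 lists of 6000 loci, X was called in 100% of lists, against 0% with no change planted. Those loci were drawn independently in proportion to gene numbers, as the test assumes. The simulation therefore does not show how often clustered loci would give a false call. With 40 planted copies among 60 overlapping pairs, a median of 40 coincident pairs was found. With the 5′-most span doubled in 1000 loci, 100% of 50 lists passed the threshold, against 0% with no change. Each of these simulated loci held only its end peaks, with spans drawn before doubling from the listed spans of up to 1000 nt. The wider listed spans were therefore not covered by that simulation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.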

Results

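To locate m6A in the RNA of mouse bone marrow-derived dendritic cells, immunoprecipitated RNA (2 libraries) was compared with input RNA (2 libraries), and the authors listed 9028 peaks. Of these, 4341 were on the plus strand and 4687 on the minus strand. The 19 autosomes and X held 9018 peaks, the mitochondrial chromosome held 9, and 1 lay on a contig outside the chromosomes. No listed peak was on Y. The list gave 1 set of peaks without a score, so every value below describes that set and has no replicate error, and counting intervals are given where a share was computed. Merging rows that overlapped on either strand left 8800 separate intervals.

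Most peaks spanned up to 1000 nt, a limit set for counting, and the others formed a long tail of wider spans. The median span was 660 nt (95% interval of the median 631 to 689 nt), with quartiles of 331 and 2666.5 nt. Spans of up to 1000 nt made up 59.3% of peaks (5354 peaks, 95% interval 58.3% to 60.3%) and had a median of 388 nt. The other 3674 peaks, 40.7% of the list, had a median span of 3590 nt, and 688 peaks exceeded 10000 nt. The widest 5 were on chromosome 6 at 32829070 to 33026351 on the minus strand (197 kb), chromosome 2 at 52747962 to 52932309 on the plus strand (184 kb), chromosome 3 at 67088192 to 67259094 on the plus strand (171 kb), chromosome 2 at 16361624 to 16516977 on the plus strand (155 kb), and chromosome 15 at 53059644 to 53208329 on the minus strand (149 kb). All positions are on GRCm39. Among the 1821 peaks of up to 300 nt, 83.1% had a span that was a whole multiple of 30 nt or 1 nt more, where 6.67% would be met by chance. Among the 2099 peaks over 3000 nt the share was 6.67%.

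**Figure D1:**
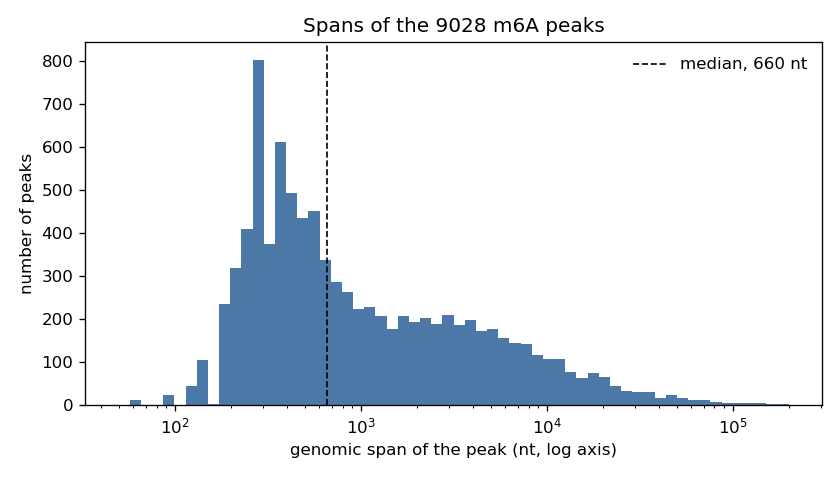
Number of peaks (vertical axis) by genomic span in nt (horizontal log axis) for all 9028 peaks, with the median of 660 nt as a dashed line. Narrow spans form the main mode, and 40.7% of peaks lie beyond 1000 nt.

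On the mitochondrial chromosome, 8 of the 13 protein-coding genes had a peak of their own. Of the 7 ND genes, which encode subunits of NADH dehydrogenase in the respiratory chain, 5 had a peak (ND1, ND2, ND4, ND5 and ND6) and ND3 and ND4L had none. Of the other 6 genes, COX1, a subunit of cytochrome c oxidase, ATP8, a subunit of ATP synthase, and CYTB, cytochrome b, had a peak, and COX2, COX3 and ATP6 had none of their own. The difference between 5 of 7 and 3 of 6 did not pass Fisher's exact test (two-sided p = 0.592). No base of the 2 mitochondrial ribosomal RNA genes, mt-Rnr1 and mt-Rnr2, lay under a peak, in libraries from which ribosomal RNA reads had been filtered.

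Mitochondrial peaks differed in how much of each gene they covered. ND2 (MT 3914 to 4951), ND5 (MT 11742 to 13565) and ND6 (MT 13552 to 14070, the one minus-strand peak) were covered over 100% of their length. The ND4 peak (MT 10287 to 11544) covered 91.3% of the gene, the ATP8 peak (MT 7795 to 7969) 85.8%, and the CYTB peak (MT 14643 to 15288) 56.5%. The COX1 peak (MT 6605 to 6872) covered 17.3% of the gene, at its 3′ end. ND1 had 2 separate peaks, one over the first 300 nt of the gene (MT 2751 to 3050, 31.3% of its length) and one over the last 360 nt (MT 3348 to 3707, 37.6%). The ATP8 peak reached 43 nt into ATP6, which overlaps it. In all, 8 of the 9 peaks ended at the annotated 3′ end of their gene and 4 began at its 5′ end. Among peaks that reached 1 end only, 5 reached the 3′ end and 1 the 5′ end, which did not pass an exact sign test (two-sided p = 0.219). Of the 18 edges, 12 lay at a gene edge to the base, so these edges may follow the gene annotation used in the calls. The tally and the sign test therefore cannot show where in a gene the enrichment lay. The peaks were also too few for a firm statement about position.

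**Figure D2:**
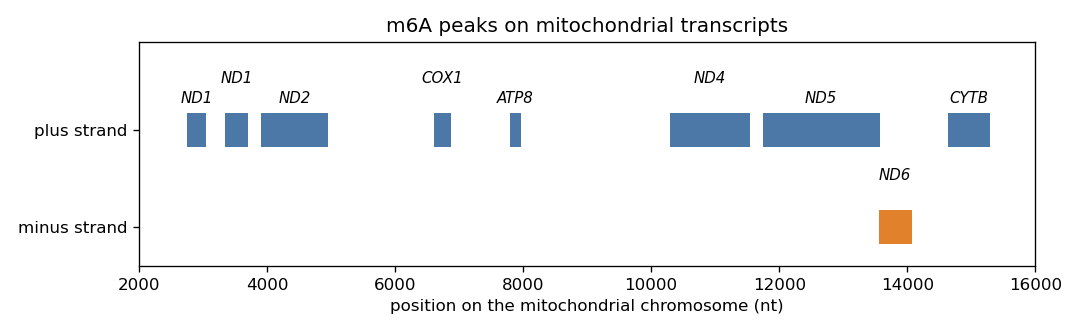
The 9 peaks on the mitochondrial chromosome, drawn to scale by position in nt (horizontal axis) and strand (vertical axis), each named for its gene. ND2, ND5 and ND6 are covered whole, ND1 carries 2 peaks, and ND6 is on the minus strand.

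Loci with peaks were spread over the autosomes and were rarer on X and on chromosome 7 than gene numbers would give. Joining same-strand peaks over gaps of up to 10 kb gave 6224 loci, or 288 per 1000 protein-coding genes. Chromosome X had 148 loci (200 peaks) for 966 protein-coding genes, or 153 per 1000 genes (95% interval 130 to 180), which was 0.532 times its share of genes (interval 0.451 to 0.624, exact binomial test, Benjamini-Hochberg adjusted p = 7.28e-17). Chromosome 7 had 409 loci for 2030 genes, a ratio of 0.700 (interval 0.636 to 0.769, exact adjusted p = 1.58e-14). Chromosome 1, with 408 loci for 1204 genes, lay above its share at 1.18 (interval 1.07 to 1.29, exact adjusted p = 0.00601), as did chromosome 10, with 333 loci for 1001 genes, at 1.16 (interval 1.04 to 1.28, adjusted p = 0.0395). The ratios of the other 16 chromosomes ran from 0.866 to 1.16 and did not pass the threshold (lowest exact adjusted p = 0.0703). The number of chromosomes past it depended on the counting, from 2 with peaks of up to 1000 nt or with runs of consecutive rows to 8 with peaks over 1000 nt, 10 with single peaks counted and 11 with all gene types counted. The excess on chromosome 1 did not pass (ratio 1.09, exact adjusted p = 0.297) when olfactory, vomeronasal and taste receptor families and predicted genes were left out of the gene count, whereas X (0.551), 7 (0.816) and 10 (1.19) stayed past it. The excess on chromosome 10 did not pass when peaks were joined over up to 20000 nt (ratio 1.14, exact adjusted p = 0.115).

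**Figure D3:**
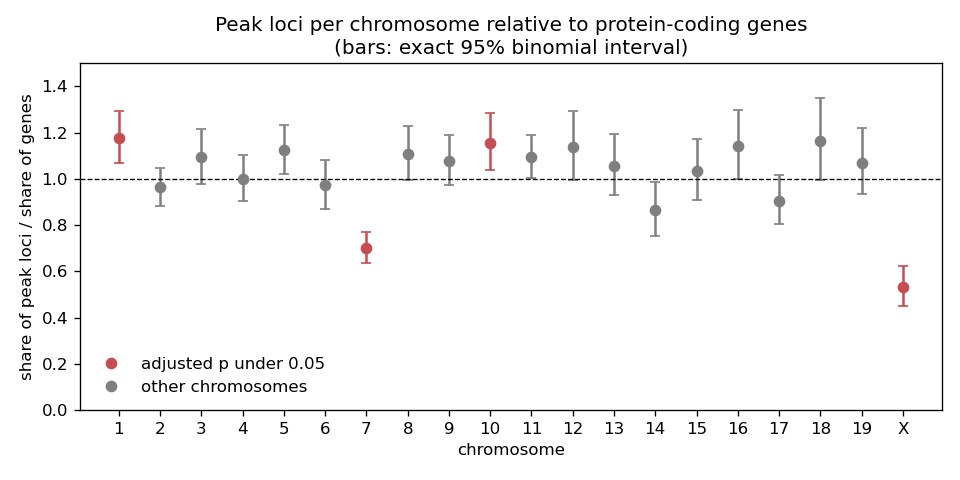
Share of peak loci divided by share of protein-coding genes (vertical axis) for each chromosome (horizontal axis), with exact 95% binomial intervals as bars and the 4 chromosomes past the threshold in red. X (0.532) and 7 (0.700) lie below 1, and 1 (1.18) and 10 (1.16) above it.

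Of the windows of 1 Mb along the autosomes and X, 1607 held a peak, and the median of these held 4. The densest window was on chromosome 10 at 80000001 to 81000000, with 37 peaks in 23 loci (17 peaks on the plus strand and 20 on the minus strand). Windows on chromosome 7 at 127000001 to 128000000 and chromosome 9 at 44000001 to 45000000 held 36 peaks each. The chromosome 7 window had 27 on the plus strand and 9 on the minus strand, and the chromosome 9 window had 10 and 26. The next were on chromosome 19 at 5000001 to 6000000, with 33 peaks, and chromosome 10 at 128000001 to 129000000, with 29. Windows were ranked by raw peak counts, without adjustment for the number of genes in them, so the ranking does not tell clustered peaks from dense genes.

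Most loci had a single peak. Of the 6224 loci, 4362 (70.1%) had 1 peak, 1281 (20.6%) had 2, 379 had 3 and 85 had 5 or more. Loci with 2 or more peaks made up 29.9% (95% interval 28.8% to 31.1%) and held 51.6% of peaks. That share followed the joining distance, at 15.6% for gaps of up to 1000 nt and 44.5% for gaps of up to 50000 nt. The locus with the most peaks was on chromosome 15 at 98731918 to 98761958, with 10 peaks of 181 to 1859 nt. Chromosome 5 at 41945930 to 41990028 had 9 separate peaks. Chromosome 1 at 133547798 to 133561574 also had 9 listed peaks, but these overlapped and merged into 3 intervals. The 4 loci with 8 peaks were on chromosome 4 at 123279466 to 123328911, chromosome 9 at 44715881 to 44741401, chromosome 12 at 112739137 to 112749467, and chromosome 17 at 25101941 to 25146256. All 7 of these loci were on the minus strand (exact binomial p = 0.0156, not adjusted). The limit of 8 peaks was chosen after seeing the data, so that p is no firm evidence of a strand difference. Among the 85 loci with 5 or more peaks, 50 were on the minus strand (58.8%, 95% interval 47.6% to 69.4%, exact binomial p = 0.128).

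The strands were nearly balanced. The minus strand had 3193 of the 6224 loci, 51.3% (95% interval 50.1% to 52.6%), which passed an exact binomial test against 50% narrowly (p = 0.0413). Of 6 alternatives, 4 kept the call, with the lowest p when single peaks were counted (51.95%, exact p = 0.000219), and 2 did not, with gaps of up to 20000 nt (51.3%, exact p = 0.0577) or 50000 nt (50.9%, exact p = 0.200) joined. By chromosome the minus-strand share ran from 46.6% on chromosome 16 to 58.0% on chromosome 15. After Benjamini-Hochberg adjustment 0 of 20 chromosomes passed the exact binomial test (lowest adjusted p = 0.0815, on chromosome 7), and 4 had an unadjusted p under 0.05.

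Within loci, the 5′-most peak had a wider genomic span than the 3′-most peak. Over 1839 loci with different peaks at the 2 ends, the median span was 869 nt at the 5′ end and 569 nt at the 3′ end. Spans over 1000 nt made up 46.9% of 5′-most peaks and 34.3% of 3′-most peaks. The 5′-most peak was the wider one in 1058 loci and the 3′-most in 758, with 23 ties, so that it was wider in 58.3% of loci without a tie (95% interval 56.0% to 60.5%, exact sign test, p = 2.03e-12). The share was 55.2% on the plus strand and 61.2% on the minus strand. Among the 694 loci in which both end peaks spanned up to 1000 nt, the 5′-most was wider in 335 and the 3′-most in 336 (49.9%, interval 46.1% to 53.8%, exact p = 1). That subset was chosen by the span compared, and leaves out the wide spans that were more common at the 5′ end.

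**Figure D4:**
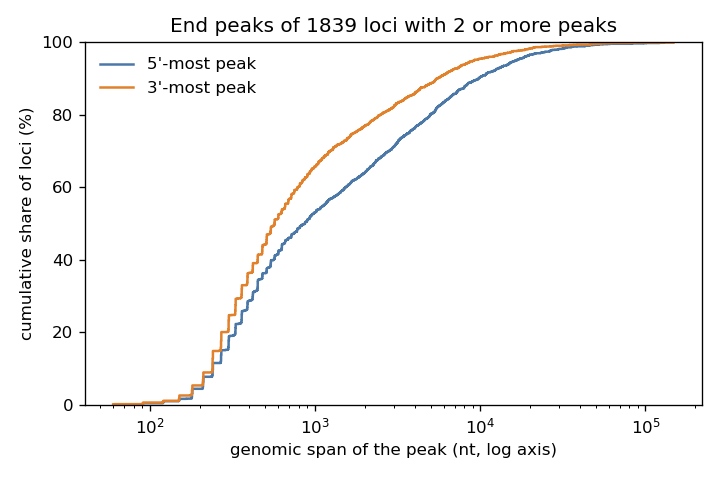
Cumulative share of the 1839 loci in percent (vertical axis) by genomic span in nt (horizontal log axis) for the 5′-most and the 3′-most peak of each locus. The medians are 869 and 569 nt, and 46.9% of 5′-most against 34.3% of 3′-most peaks exceed 1000 nt.

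Some stretches were listed on both strands. Between peaks of up to 1000 nt, 65 pairs on opposite strands overlapped, against a median of 7 (range 1 to 18) in 1000 lists with shifted minus-strand peaks (permutation p = 0.000999, the smallest these draws can give). In 37 of the 65 pairs, 56.9% (95% interval 44.0% to 69.2%), both edges agreed within 30 nt, where 2.64 pairs were expected from random overlap (permutation p = 0.0001, the smallest 10000 draws can give). The share depended on the limits, at 20% with edges within 15 nt and 69.2% within 60 nt. It was 35.2% for peaks of any width and 76.3% for peaks of up to 500 nt. One interval, on chromosome 8 at 70745964 to 70746233, was listed on both strands with identical edges. Chromosome 11 at 95721617 to 95723648 held 5 coincident pairs, from 5 plus-strand and 3 minus-strand peaks. Chromosome 1 at 155882435 to 155941525 and chromosome 5 at 24792964 to 24797494 held 2 each. The coincident pairs involved 72 peaks, 0.798% of those on the autosomes and X. With spans of any width, 108 opposite-strand pairs overlapped against a median of 94 in shifted lists (range 61 to 130, permutation p = 0.0819), which did not pass. That total joined the 65 narrow pairs with 43 pairs that included a span over 1000 nt, which were fewer than the median of 86 in shifted lists (range 58 to 125, one-sided permutation p = 0.000999, the smallest these draws can give). On the same strand, 130 pairs overlapped, involving 227 peaks.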

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

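All alternatives here were chosen after seeing the data, since none of the planned ones could be run without transcript models, sequence or a peak score. No paired analysis was possible because the deposited list has no value for any single library, and leaving out a replicate was impossible for the same reason. Depth is unknown, so no limit on weak peaks can be given. The direction and call for X (0.469 to 0.602 times its share of genes) and for chromosome 7 (0.564 to 0.816) held in all 10 alternatives each. The number of loci (4832 to 7533), of merged intervals (8625 to 8906) and of mitochondrial genes with a peak (7 to 9) stayed within 1.5 times the reported values. The share of coincident opposite-strand pairs ran from 20% with edges within 15 nt to 76.3% for peaks of up to 500 nt, past the threshold in all 4 alternatives. The cause was not tested for the changes below except where stated.

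Loci with 2 or more peaks were 15.6%, 24.5%, 35.7% and 44.5% for gaps of up to 1000, 5000, 20000 and 50000 nt and 39.9% for runs of consecutive rows, a change that follows from the joining rule itself. Chromosome 1 no longer passed without receptor families and predicted genes (1.09), with all gene types counted (1.09), with peaks of up to 1000 nt (1.13) and with runs of rows (1.14). Chromosome 10 no longer passed for gaps of 20000 nt (1.14) and 50000 nt (1.10), peaks of up to 1000 nt (1.18), peaks over 1000 nt (1.08) and runs of rows (1.13). The number of chromosomes past the threshold was 7 for gaps of 1000 nt and of 5000 nt, 10 with single peaks counted, 11 with all gene types, 2 with peaks of up to 1000 nt, 8 with peaks over 1000 nt and 2 with runs of rows, against 4. The 5′-most peak was wider in 49.9% of loci when both end peaks spanned up to 1000 nt, an almost even split (335 loci against 336). The share was 51.1% when both spanned up to 500 nt. Neither share passed the threshold. Both limits act on the span compared. The 5′-most peak was wider in 55.2% to 63.1% of loci in the other 10 alternatives. The minus-strand share no longer passed for gaps of 20000 nt (51.3%) and 50000 nt (50.9%), and passed in the other 4 alternatives. Among these was the count of single peaks, which repeats a locus for each of its peaks. Opposite-strand overlaps numbered 108 for peaks of any width, against 65. The median span was 388 nt among peaks of up to 1000 nt, by construction.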

Other observations

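Of the tests below, all those on X and chromosome 7, on coincident edges and on joining over 1000 nt were chosen after the result was seen. The count of overlapping pairs against shifted lists and the test on narrow end peaks had their outcome predicted first. The prediction for shifted lists set no limit on the span. The split into narrow pairs and pairs with a span over 1000 nt was not part of it.

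Fewer loci carried a peak on X than its share of genes. Receptor families and predicted genes in the gene count did not account for it, since without them the ratio was 0.551 (interval 0.467 to 0.646). Joining peaks into loci did not account for it either, since with single peaks counted the ratio was 0.497 (interval 0.431 to 0.569). That interval treats peaks of 1 locus as independent and is too narrow. On chromosome 7 leaving out the same genes moved the ratio from 0.700 to 0.816 (interval 0.741 to 0.896), so these genes may explain part of that deficit but not all of it. Lower expression of X-linked genes in these cells, and a gene content of X used in other tissues, stay open because the list holds no expression values.

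The wider spans at the 5′ end of loci were weighed against intron content. With both end peaks of up to 1000 nt the share with the wider 5′-most peak was 49.9% (interval 46.1% to 53.8%), against 58.3% over all loci. A limit on the span that is compared can lower the share by itself, so this test does not decide whether wide spans cross introns. The list has no block columns, so no intron can be read from it directly. Spans of up to 300 nt lay on the 30-nt step in 83.1% of peaks, and spans over 3000 nt in 6.67%, the share met by chance. Wide spans were therefore mostly not runs of whole 30-nt steps. Included introns would have that effect, but so would edges placed at gene ends, and the step cannot tell them apart. Joining peaks over gaps longer than 1000 nt did not account for the difference, since the share was 57.4% (interval 54.5% to 60.3%) with gaps of up to 1000 nt. Peaks of neighbouring genes that lie closer or overlap are still joined at that limit, so this test does not exclude them. Intron content, joined peaks of close neighbouring genes, and a difference in the length of the enriched RNA between the 2 ends all stay open.

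Peaks listed on both strands with nearly the same edges may be 1 enriched stretch listed once for each of 2 gene models on opposite strands. In 56.9% of the narrow overlapping pairs both edges agreed within 30 nt (37 pairs, where random overlap gave 2.64). Random placement of peaks did not account for the 65 narrow pairs, since no shifted list had more than 18. The shifts do not keep peaks within genes, so independent peaks of overlapping or neighbouring genes were not tested. The 43 pairs that include a span over 1000 nt were fewer than in any shifted list (58 to 125), so the total of 108 pairs joins an excess with a deficit. That total, the count the prediction was made for, lay within the shifted lists (61 to 130), as predicted for overlap by position alone. Of the 14 coincident pairs whose loci both had 2 or more peaks, 7 paired the 3′-most peak of one locus with the 5′-most of the other, 7 involved an inner peak, and 0 paired 3′ ends or 5′ ends. These 14 pairs came from 8 pairs of loci, 3 of which gave 9 of them, so they are not independent cases. On opposite strands, the 3′ end of one locus faces the 5′ end of another that covers the same stretch. The tally therefore partly follows from how the ends are defined. Methylation of both RNAs at the same place stays open, since the strand of the reads is not in the list.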
